A study of Mus musculus with 31 samples.

How the data were processed

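RNA (200 ng) from whole lungs of 31 mice was labelled with Cy3 and hybridised to Agilent mouse arrays of 62976 spots, 3671 of them controls. Images were read by the authors with Agilent Feature Extraction 10.5.1.1. Per the file headers, the scanner files hold for each spot an intensity. The mean and background signals are as measured. The processed signal had been corrected for background and spatial trend by the software and replaced by a surrogate for dim spots. Flags are 0 or 1. The deposited table of the authors holds log2 values. Its sorted columns differed by at most 0.0179, so they share a distribution as after quantile normalization. How the authors treated background there is not stated. Mice were grouped by treatment (saline or oleic acid) and time into 12 groups, as the labels give them, and every array was matched to its scanner file and its column.

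Values were computed from the scanner files in R 4.3.3 with the data.table package (version 1.17.8). The processed signal of the 59305 non-control spots was taken on the log2 scale and the 75th percentile of the array was subtracted. Spots with an outlier flag were left out and the spots of each of 55681 probes were averaged. Probes were kept if they lay well above background on every array of at least 1 group, and each gene was represented by its kept probe with the highest mean. Probes took current symbols through the RefSeq accession (26582 probes) or the file's own symbol (3094), and 26005 had no current symbol and stayed as separate features. In limma 3.58.1 (statmod 1.5.0) the 12 group means were fitted to all 31 arrays with empirical Bayes moderation, since groups of 2 or 3 arrays need a common estimate of spread. Oleic acid was compared with saline at each of 6 times, as the mean over 1 to 4 h, as the mean over 18 and 24 h and as the difference of those means. Saline mice of 18 and 24 h were compared with those of 1 to 4 h, so there were 10 comparisons. Within each, p-values were adjusted by the Benjamini-Hochberg method over 24974 features, with a threshold of 0.05, and intervals are moderated 95% intervals.

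The 43 gene lists covered inflammation, stress, lipid metabolism, barrier function, lung and blood cell types and neighbouring tissues. They were tested by camera with the preset correlation of 0.01 and with an estimated correlation, each adjusted over the 43 lists, and by fry. Members were also counted as adjusted over the list alone. Of the list results over 10 comparisons, 48 are described, and these were chosen after the list results were seen. In the preset test with 31 arrays between 6 and 13 lists were called per comparison, and with an estimated correlation 0 were called in any comparison with 31 or 29 arrays. The deposited table gave calls for 2, both at 1.5 h. Fry called 0 lists, except 7 with 29 arrays and 8 in the deposited table for saline mice over time. Named genes followed a rule. For the means over 1 to 4 h and over 18 and 24 h the 10 largest rises and 10 largest falls among passing genes whose oleic acid arrays all lay on 1 side of the saline arrays at every time were taken. For the other comparisons the 5 largest of each were taken, at single times without overlap of the groups. From each described list up to 4 measured members with the smallest p, and any member given as not passing, could be named. Genes known only by clone, model or accession names were left out of it, and any other feature is said to have been chosen after its values were seen. The groups, model, thresholds, lists, rule for naming and 15 alternative settings with the omission of each array were fixed before the data were examined. Those settings are normexp background correction with an offset of 50, quantile normalization, median centring, the deposited table, other filters and probe summaries, kept outlier spots, slide as a fixed or random term, replicate number as a block, array weights, other moderation, stricter thresholds, and other control groups.

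The 11 settings added after seeing the data include the fit without oleic acid 1.5 h replicate 3 and oleic acid 3 h replicate 2, whose spike-in slope lay under 0.8 or over 1.2. The arrays left are called 29 arrays throughout. Others leave out also the 5 arrays with over 70% of spots above background or take that share as a covariate. Comparisons of time within oleic acid mice and within slides, and F tests over times, were added in the same way. Random groupings were also compared with the real one, 100 in all with the real one included, or 10 at 1 h. Oleic acid and saline arrays were split within times. For late against early saline mice the saline arrays were divided across times. Recovery was tested on simulated data, in which 66 or 67 genes of 24974 were raised or lowered at each size. The simulated noise was normal and independent between genes, with a spread per gene that was the same on every array. Arrays of poor quality, slides, missing values and correlated genes were not simulated. Recovery in the measured arrays may thus differ from the shares that follow. For a 4-fold change over 1 to 4 h 91% were called with 31 arrays and 94% with 29, and at 4 h 35.8% and 76.1%. For a 2-fold change, nearer to most differences described, 31 arrays recovered 56.7% over 1 to 4 h, 10.4% over 18 and 24 h, 1.5% at 1 h and 0% at 4 h, so a count of 0 does not rule out changes of that size. With 29 arrays these shares were 82.1%, 67.2%, 32.8% and 35.8%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays, 2 or 3 per group, limits the precision of every value.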

Results

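Whole lungs of 31 female C57BL/6 mice aged 6 weeks were profiled on 31 Agilent mouse arrays with 1 dye channel, 1 mouse per array. Oleic acid, a fatty acid that damages the pulmonary endothelium when it is given into a vein, was injected into the tail vein of 18 mice at 1.2 µl per g of body weight in 200 µl. Saline (200 µl) was given to 13 mice. Lungs were taken at 1, 1.5, 3, 4, 18 and 24 h, with 3 oleic acid mice at every time, 3 saline mice at 1 h and 2 saline mice at each other time. The series asks how the lung transcriptome develops over time in this model of acute lung injury. Expression values are on the log2 scale, as the processed signal relative to the 75th percentile of the array, and 24974 genes or unnamed transcripts were tested, 16617 of them with a current gene symbol. The number of arrays limits the precision, and ranges in parentheses after a difference are 95% intervals.

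Signal quality differed between arrays. The slope of signal against spike-in amount lay between 0.937 and 1.06 on 29 arrays, but was 1.66 on oleic acid 1.5 h replicate 3 and 0.751 on oleic acid 3 h replicate 2. The former array held 15585 spots with an outlier mark, against at most 365 on the 29 arrays, and on the latter 99.64% of spots lay well above background. Both stayed in the fixed comparisons, and each comparison was also made with the 29 other arrays, an alternative chosen after seeing the data. A further 5 arrays had between 72.19% and 82.39% of spots above background. They were saline 1 h replicate 1, saline 1.5 h replicate 2, saline 18 h replicate 2, oleic acid 1 h replicate 2 and oleic acid 18 h replicate 2. The remaining 24 had between 51.18% and 66.19%. The arrays were scanned on 4 slides that followed time. Slide 1 held every 1 h array and slide 2 most of 1.5 h and 3 h. Slide 3 held every 4 h array with the saline 18 h arrays, and slide 4 held the oleic acid 18 h arrays with all of 24 h.

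**Figure D1:**
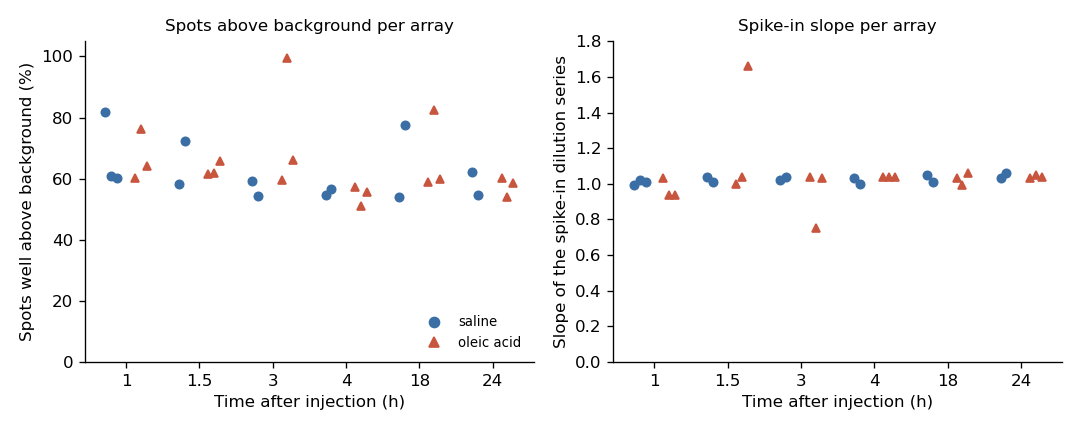
The share of spots well above background (%) and the slope of log signal against log spike-in amount are plotted for each of the 31 arrays by time, with saline and oleic acid mice in different colours. The slopes of 1.66 at 1.5 h and 0.751 at 3 h stand apart from the 29 others, which lie between 0.937 and 1.06.

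Over the first 4 h, the question was which genes oleic acid alters while the injury develops. No gene passed in the mean over 1, 1.5, 3 and 4 h. In the fit to all arrays, the 95% intervals of mediators often followed in lung inflammation held 0. Il6, a cytokine that drives the acute phase response, differed by -0.35 (-1.40 to 0.71; 12 oleic acid and 9 saline arrays), and Tnf, an early macrophage cytokine, by 0.35 (-0.38 to 1.08). Ptgs2, the inducible cyclooxygenase, differed by 0.24 (-0.35 to 0.84). Hmox1, the inducible haem oxygenase, differed by -0.14 (-0.53 to 0.26). In limma, 0 of 24974 genes had an adjusted p under 0.05, 880 had an unadjusted p under 0.05, and the smallest adjusted p was 0.972. This fit includes oleic acid 1.5 h replicate 3 and oleic acid 3 h replicate 2, with spike-in slopes of 1.66 and 0.751. Its median standard error over all genes was 0.262, against 0.145 with 29 arrays. Intervals of these mediators with 29 arrays are not given in the text, so whether they also hold 0 is left open.

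Among inflammatory genes over 1 to 4 h, none of the 15 measured cytokines and growth factors passed, and their median was 0.08, a sign that turned with normexp background correction, quantile normalization and median centring. The saline side includes saline 4 h replicate 2, whose mean over cytokine and chemokine genes, 0.42, was the highest of all 31 arrays. Il12b, a subunit of interleukins that steer T cells, had a difference of 0.86 (0.03 to 1.70), which turned to -0.15 with normexp, and Areg, an epidermal growth factor receptor ligand, one of -0.55 (-1.21 to 0.11). The 20 chemokines had a median of -0.10, and none passed. Cxcl1 and Cxcl2, which attract neutrophils, differed by -0.34 (-1.76 to 1.08) and -0.10 (-0.98 to 0.78). Ccl2, which attracts monocytes, differed by 0.21 (-0.49 to 0.90). Cxcl13, which attracts B cells, differed by 0.83 (0.15 to 1.51). Of 26 neutrophil markers 5 lay above 0, with a median of -0.11 that was 0.04 with 29 arrays. Over all genes the median was -0.087 with 31 arrays and -0.025 with 29. The chemokine and neutrophil medians with 31 arrays thus lay near that of all genes. Lcn2, an iron-scavenging protein of neutrophil granules, had a difference of -0.58 (-1.15 to 0.00) and the interferon-inducible Slfn4 one of 0.38 (-0.24 to 0.99). The 19 acute phase genes had a median of -0.21, and 0.01 in the deposited table. Serum amyloid genes gave the widest values of this list, with -2.37 for Saa2 (-4.68 to -0.05) and -1.16 for Saa1 (-2.65 to 0.34).

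Genes that handle the injected fatty acid did not pass either over 1 to 4 h. The 35 measured targets of the fatty acid receptors PPAR had a median of -0.16, which turned to 0.01 with 29 arrays and to 0.05 in the deposited table. Angptl4, an inhibitor of lipoprotein lipase, differed by -0.36 (-1.16 to 0.44). Plin2, a lipid droplet coat protein, differed by -0.37 (-0.92 to 0.17). Cpt1b, which brings fatty acids into mitochondria, differed by -0.65 (-1.31 to 0.01). The 21 oxidative stress genes under Nrf2 had a median of -0.04 and of 0.10 with 29 arrays, and quantile normalization and the deposited table also gave medians above 0. Slc7a11, the cystine transporter of glutathione synthesis, lay above background on 6 of 12 oleic acid arrays and on no saline array here, so no size is given. Nqo1, a quinone reductase, had a difference of 0.25 (-0.45 to 0.94).

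Markers of the airway and of the alveolar barrier were read in the same way. The 20 club cell markers had a median of 0.12, which median centring turned to -0.04, and the 25 ciliated cell markers one of -0.05, which turned to 0.13 with 29 arrays and was also above 0 with normexp and in the deposited table. Reg3g, an antibacterial lectin, had a difference of 0.82 (-0.05 to 1.68). Muc5ac, the airway mucin of goblet cells, differed by 0.53 (0.09 to 0.97). Scgb1a1, the secretory protein of club cells, gave -0.65 (-1.30 to -0.01), against 0.00 in the deposited table. With 29 arrays the preset camera test called the club list (adjusted p = 0.000298, and adjusted p = 0.629 with an estimated correlation), the ciliated list (adjusted p = 0.000404, and adjusted p = 0.834 with an estimated correlation) and the Nrf2 list (adjusted p = 0.00485, and adjusted p = 0.834 with an estimated correlation). Endothelial cells line the vessels that oleic acid meets first, and their 28 markers had a median of -0.26, -0.13 with 29 arrays and -0.06 in the deposited table. Their preset camera test gave an adjusted p = 0.0192, and an adjusted p = 0.961 with an estimated correlation. The endothelial transcription factor Erg differed by -0.49 (-0.92 to -0.07), the adrenomedullin receptor Calcrl by -0.47 (-0.88 to -0.06) and the angiopoietin receptor family member Tie1 by -0.46 (-0.91 to 0.00). The 20 genes of ion and water transport had a median of -0.14 and the 24 junction genes one of -0.17, beside -0.087 over all genes, with no gene passing. Among them Scnn1a, a subunit of the sodium channel that clears alveolar fluid, differed by -0.20 (-0.72 to 0.32), the water channel Aqp5 by -0.26 (-0.81 to 0.29), the endothelial tight junction protein Cldn5 by -0.51 (-1.06 to 0.05) and the epithelial tight junction protein Ocln by 0.42 (-0.02 to 0.86).

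**Figure D2:**
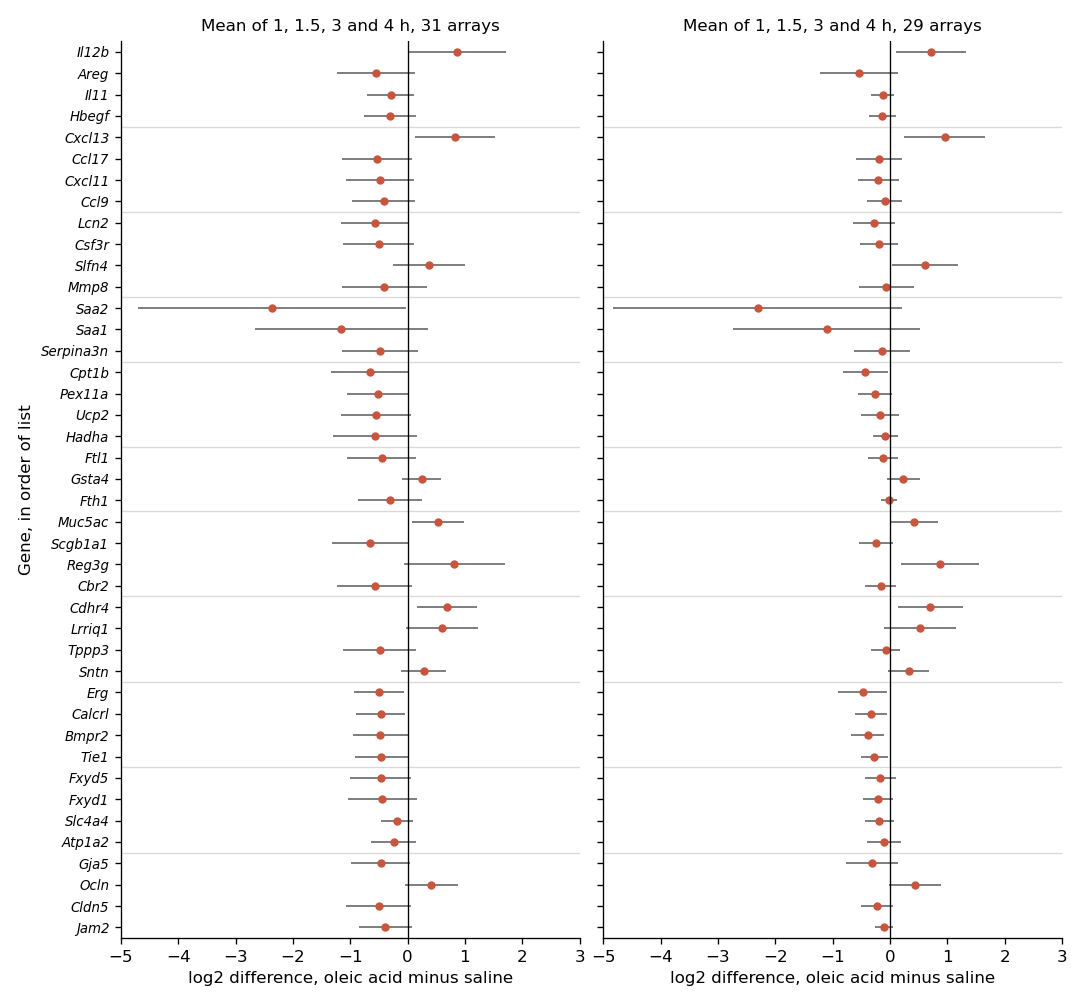
The log2 difference between oleic acid and saline over 1 to 4 h is plotted for members of the fixed lists, with points for the estimate and bars for the 95% interval, from 31 and from 29 arrays. No gene shown passed the test; Areg lies at -0.55 and Saa2 at -2.37 with 31 arrays.

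Adjusted over the list alone, 0 members of the 43 lists passed over 1 to 4 h with 31 arrays, against 3 with 29 arrays and 18 in the deposited table. Across all 43 lists the preset camera test called 8, and 0 with an estimated correlation, and the sign of the median differed between 31 and 29 arrays for 16. The median standard error over all genes was 0.262 with 31 arrays and 0.145 with 29, where limma called 0 genes with 1848 at an unadjusted p under 0.05; the deposited table gave 0 with 2234. Array weights estimated in limma, a fit that stopped before convergence, called 2062 genes with 31 arrays and 1 with 29.

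At 18 and 24 h, the comparison asked what remained or appeared by then. No gene passed in the mean of these times over 6 oleic acid and 4 saline arrays. At 18 h the saline arrays were on slide 3 and the oleic acid arrays on slide 4. Treatment and slide thus cannot be told apart in the 18 h part of this mean. Values above 0, none passing, included 1.13 for Cxcl9 (standard error 0.66) and 0.78 for Cxcl10 (-0.13 to 1.70), which attract T cells, and 1.13 for Slfn4 (0.24 to 2.02). Il6 differed by 0.33 (-1.20 to 1.87) and Tnf by 0.21 (-0.85 to 1.27). Il1b, a cytokine matured by the inflammasome, differed by 0.52 (-0.81 to 1.84). In limma, 0 genes had an adjusted p under 0.05 and 163 an unadjusted p under 0.05, with a smallest adjusted p of 0.149. The 163 are 0.653% of the genes, below the share of 0.05 expected when no gene differs. Across all genes the median difference was -0.067.

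Of 26 neutrophil markers 18 lay above 0 at 18 and 24 h, with a median of 0.18 and a preset camera adjusted p = 0.00142, against an adjusted p = 0.997 with an estimated correlation. Clec4e, a receptor for mycobacterial and damage-associated lipids, differed by 0.56 (-0.28 to 1.41). Mrgpra2b, a Mas-related receptor of neutrophils, differed by 0.73 (-0.13 to 1.60). The 27 interferon response genes held 22 above 0 and a median of 0.11, with a preset adjusted p = 0.00142 and an adjusted p = 0.997 with an estimated correlation. Irf7, the regulator of type I interferon genes, differed by 0.38 (-0.13 to 0.89). Oas3, a sensor of double-stranded RNA, differed by 0.52 (-0.29 to 1.32). Zbp1, a sensor of Z-form nucleic acids, differed by 0.48 (-0.40 to 1.35). Among 35 PPAR targets 24 lay above 0, with a median of 0.13, a preset adjusted p = 0.00142 and an adjusted p = 0.997 with an estimated correlation. The mitochondrial carnitine carrier Slc25a20 differed by 0.50 (0.03 to 0.97) and the acyl-CoA thioesterase Acot2 by 0.41 (-0.17 to 1.00). Cpt1a, the gate of fatty acid oxidation, differed by 0.39 (-0.37 to 1.14). The 14 mesothelial markers had a median of 0.15 (preset adjusted p = 0.00926, and adjusted p = 0.997 with an estimated correlation). Differences were 0.55 for Lrrn4 (-0.03 to 1.13) and 0.43 for Upk3b (-0.19 to 1.05). The 15 cytokines and 20 chemokines had medians of 0.07 and 0.02, which both turned with normexp, and the 27 alveolar type 2 markers one of -0.14, which median centring turned to 0.11. Scd1, a fatty acid desaturase used in surfactant lipid synthesis, differed by -0.45 (-1.28 to 0.38), and Ccl2 by 0.27 (-0.74 to 1.27). No member of these lists passed, over all genes or adjusted over the list alone. The values of these lists include the 18 h difference, in which treatment and slide cannot be told apart.

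With 29 arrays limma called 2 features lower at 18 and 24 h, both chosen after their values were seen and both above background on no oleic acid array, so no size is given. They were a probe without a gene name on chromosome 11 (adjusted p = 0.00373, against 0.149 with 31 arrays and 0.971 in the deposited table) and a probe of an intergenic RNA on chromosome 9 (adjusted p = 0.00373, against 0.247 and 0.971). Over the settings tried the count ran from 0 to 49, with 4 by array weights. Without saline 18 h replicate 2 the 31 arrays gave 4 genes, without saline 24 h replicate 1 they gave 1, and without oleic acid 24 h replicate 3 also 1.

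Whether the effect of oleic acid differed between 18 and 24 h and 1 to 4 h was tested as a difference of differences. No gene passed. The preset camera test called 10 of 43 lists, all higher, and 3 of them are described here, with medians that were smaller for 2 of them with 29 arrays. Of 20 immediate early genes, which respond within minutes to growth and stress signals, 19 lay above 0 with a median of 0.46 (0.18 with 29 arrays), a preset camera adjusted p = 1.14e-05 and an adjusted p = 0.927 with an estimated correlation. The difference of effects was 1.08 for Klf2, a flow-responsive endothelial transcription factor (0.02 to 2.13), 0.92 for Dusp1, a MAP kinase phosphatase (-0.29 to 2.12), and 0.81 for Fosb, a subunit of AP-1 (-0.49 to 2.10). The 35 PPAR targets had a median of 0.32 (0.08 with 29 arrays and 0.07 in the deposited table), a preset adjusted p = 0.00016 and an adjusted p = 0.927 with an estimated correlation. Differences were 0.64 for Pdk4, which shuts pyruvate oxidation (-0.42 to 1.69), and 0.62 for Ucp2, a mitochondrial carrier (-0.42 to 1.67). For the 25 genes of cholesterol synthesis the median was 0.19 (0.19 with 29 arrays), the preset adjusted p = 0.00291 and the adjusted p = 0.927 with an estimated correlation. Differences were 0.70 for the sterol demethylase Cyp51 (-0.01 to 1.41) and 0.47 for Srebf2, the regulator of this pathway (-0.17 to 1.12). In limma, 0 genes passed and 98 (0.392%) had an unadjusted p under 0.05, with 0 and 309 on 29 arrays, and adjusted over the list alone 0 members of these lists passed. Array weights called 2 genes with 31 arrays, and slide as a random term gave 0. With the 12 groups kept apart, this contrast cannot be fitted with slide as a fixed term. The saline 18 h arrays were on slide 3 and the oleic acid 18 h arrays on slide 4. Treatment and slide thus cannot be told apart in the 18 h part of this contrast.

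The single times were compared to place an effect in time, each with 3 oleic acid arrays against the saline arrays of that time. At 1 h, red cell genes and clock genes stood out among the lists. The 15 erythroid markers had a median of -1.03 (1 above 0), with -1.31 for Ahsp, the chaperone of alpha haemoglobin (-2.55 to -0.07), and a value at least 2.23-fold lower for the blood group protein Rhd, which lay above background on no oleic acid 1 h array. The mean of the list was 1.07, 1.2 and 0.23 on the saline 1 h arrays and -0.29, 0.38 and -0.33 on the oleic acid 1 h arrays. Saline 1 h replicates 1 and 2 had the highest means of the saline arrays, and replicate 3 lay within the oleic acid range. Means of -0.29 and -0.33 lay below every saline array, the lowest being -0.07 on saline 24 h replicate 2. The difference thus rests on both groups. For the erythroid list the preset camera adjusted p was 2.78e-10, against an adjusted p = 0.0632 with an estimated correlation. Adjusted over the list alone 0 passed with 31 arrays and 3, all lower, with 29. Among 17 clock genes the median was 0.58 (preset adjusted p = 0.00172, and adjusted p = 0.501 with an estimated correlation), and adjusted over the list alone 2 passed, both higher. Dbp, a clock output factor, differed by 2.89 (0.95 to 4.84). Per2, a repressor of the clock, differed by 1.65 (0.56 to 2.74). Arntl, the activator of the clock, differed by -1.30 (-2.39 to -0.20). These values rest on saline 1 h replicates 1 and 2, with Dbp at 1.13 and 1.73, while saline 1 h replicate 3 had 5.91 and the oleic acid 1 h arrays 5.78, 6.00 and 5.67. The 27 interferon genes had a median of -0.29 (preset adjusted p = 3.84e-05, and adjusted p = 0.855 with an estimated correlation). Rsad2, an antiviral enzyme, differed by -0.79 (-1.60 to 0.02). In limma, 0 genes passed at 1 h and 260 (1.04%) had an unadjusted p under 0.05 (0 and 1079 with 29 arrays), whereas array weights without convergence called 4564.

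**Figure D3:**
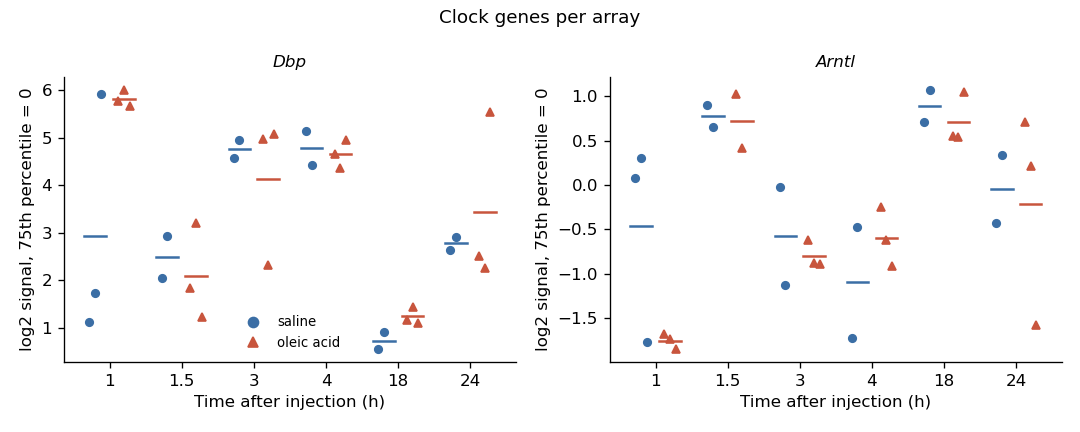
Expression of Dbp and Arntl (log2 relative to the 75th percentile of the array) is plotted for every array by time, with bars at the group means. At 1 h, saline replicate 3 lies with the oleic acid arrays, and at 24 h oleic acid replicate 3, with Dbp at 5.55, lies apart from replicates 1 and 2.

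At 1.5 h, heart muscle and platelet genes had the lower values and oxidative stress and interferon genes the higher ones. Across all genes the median was -0.12 with 31 arrays and -0.02 with 29. The 18 cardiac muscle markers had a median of -0.76 (preset adjusted p = 0.00035, and adjusted p = 0.984 with an estimated correlation). Differences were -4.03 for Nppb (-6.97 to -1.10) and -2.27 for Nppa (-4.08 to -0.46), the natriuretic peptide precursors of the heart. The mean of the list was 1.79 and 2.97 on the saline 1.5 h arrays and 1.43, 1.77 and 1.70 on the oleic acid 1.5 h arrays, so the lower value rests mostly on saline 1.5 h replicate 2, which has 72.19% of spots above background, and with 29 arrays the median was -0.65. The 19 platelet markers had a median of -0.95 (preset adjusted p = 0.000175, and adjusted p = 0.984 with an estimated correlation). Differences were -2.18 for the platelet glycoprotein Gp5 (-3.68 to -0.67) and -1.87 for Tubb1, the tubulin of platelets (-3.29 to -0.44). In the deposited table both lists passed camera with an estimated correlation, with an adjusted p = 0.029 and a median of -0.67 for the cardiac list and an adjusted p = 0.0413 and a median of -0.58 for the platelet list, and there only saline 1.5 h replicate 2 exceeded every oleic acid 1.5 h array in the mean of the cardiac list. The 21 Nrf2 genes had a median of 0.42 (preset adjusted p = 0.000251, and adjusted p = 0.984 with an estimated correlation). Gclc, which starts glutathione synthesis, differed by 1.44 (0.04 to 2.84). Slc7a11 was at least 1.53-fold higher without passing, a bound because it lay above background on no saline 1.5 h array, and had -0.13 with normexp. The 27 interferon genes had a median of 0.55 (preset adjusted p = 2.23e-08, and adjusted p = 0.984 with an estimated correlation). Differences were 1.24 for the antiviral GTPase Mx1 (0.33 to 2.15) and 2.17 for the immunity-related GTPase Iigp1 (0.11 to 4.23). Adjusted over the list alone 0 members of these lists passed with 31 arrays, and in limma 0 genes passed at 1.5 h with 832 at an unadjusted p under 0.05 (0 and 354 with 29 arrays). Array weights called 1077 genes, quantile normalization of the 29 arrays called 2, and the 31 arrays include oleic acid 1.5 h replicate 3 with its slope of 1.66. With 29 arrays the medians were -0.75 for the platelet, 0.30 for the Nrf2 and 0.25 for the interferon list.

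At 3 h, lists of lung cell types had medians far below 0, together with the oleic acid 3 h replicate 2 array and its slope of 0.751. The median over all genes was -0.22 with 31 arrays and -0.01 with 29. The 27 alveolar type 2 and surfactant markers had a median of -1.09 and the 28 endothelial markers one of -1.0, but -0.26 and -0.23 with 29 arrays. Their preset adjusted p were 1.26e-05 and 2.09e-05, and for both the adjusted p = 0.766 with an estimated correlation. Sftpb, a surfactant protein, differed by -1.41 (-2.56 to -0.25) and by -0.38 with 29 arrays, and Bmpr2, a receptor of bone morphogenetic proteins, by -1.34 (-2.30 to -0.39) and by -0.67. The 20 club cell markers had a median of -0.50 with 31 arrays, which turned to 0.41 with 29, to 0.46 in the deposited table and to 0.22 with quantile normalization (preset adjusted p = 0.434, and adjusted p = 0.884 with an estimated correlation). Adjusted over the list alone 0 alveolar type 2, 0 endothelial and 0 club cell markers passed. In limma, 0 genes passed at 3 h with 3550 at an unadjusted p under 0.05, and 0 with 1577 on 29 arrays. Without oleic acid 3 h replicate 1 the count was 141, without oleic acid 3 h replicate 3 it was 5 and without saline 3 h replicate 1 it was 1. Slide as a fixed term gave 5, or 2 with the saline groups merged, and 2 genes passed in the deposited table.

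At 4 h, fat cell genes had the higher values and neutrophil genes the lower ones. All 13 measured adipose markers lay above 0 with a median of 1.71, a preset adjusted p = 1.2e-14 and an adjusted p = 0.0744 with an estimated correlation, and adjusted over the list alone 1 passed. Adipoq, the adipocyte hormone adiponectin, differed by 2.54 (1.05 to 4.04). Car3, a carbonic anhydrase of fat and muscle, differed by 1.79 (0.26 to 3.32). Fabp4, a fatty acid carrier of fat cells, differed by 1.78 (0.25 to 3.32). The mean of the list was 1.11, 1.61 and 2.85 on the oleic acid 4 h arrays and 0.82 and 0.26 on the saline 4 h arrays. Saline arrays of 1 and 1.5 h lay between 1.09 and 2.39, which holds the first 2 of the oleic acid values. Saline 3 h replicate 2 and the saline 18 h arrays also lay in that range. Saline 3 h replicate 1, at 0.32, and the saline 24 h arrays, at 0.61 and 0.83, were near the saline 4 h arrays. Oleic acid 4 h replicate 3, at 2.85, was the highest of all 31 arrays. Low saline 4 h arrays and this high oleic acid array thus both enter the difference. The 21 genes of fatty acid synthesis had a median of 0.41 (preset adjusted p = 5.49e-05, and adjusted p = 0.976 with an estimated correlation). Differences were 0.64 for the fatty acid synthase Fasn (0.06 to 1.21) and 1.75 for the lipogenic regulator Thrsp (-0.06 to 3.56). The 35 PPAR targets, a list that also holds Fabp4, had a median of 0.16 (preset adjusted p = 0.000977, and adjusted p = 0.976 with an estimated correlation). Plin4, a lipid droplet protein, differed by 1.09 (-0.08 to 2.26). The 26 neutrophil markers had a median of -0.50 (preset adjusted p = 0.00207, and adjusted p = 0.976 with an estimated correlation). Acod1, the enzyme of itaconate synthesis, differed by -1.96 (-3.97 to 0.06), and the mean of the list was 1.81 on saline 4 h replicate 2 against 0.96 on replicate 1. In limma, 0 genes passed at 4 h and 395 had an unadjusted p under 0.05; adjusted over the list alone 0 fatty acid synthesis genes, 0 PPAR targets and 0 neutrophil markers passed. With 29 arrays 5 genes passed with 1915 at an unadjusted p under 0.05, among them Naa15, a subunit of the N-terminal acetyltransferase, which rose by 1.16 (adjusted p = 0.0442, against 1 with 31 and 0.0866 in the deposited table). The other 4, chosen after their values were seen, each lay below background on every array of 1 treatment, so their folds are lower bounds. They were Tyw3, a tRNA-modifying enzyme (at least 1.78-fold higher), the transcript D9Ertd115e (at least 1.24-fold lower) and probes without a gene name (at least 3.22-fold higher and 2.13-fold lower). Without saline 4 h replicate 1 the 31 arrays gave 2 genes and without oleic acid 4 h replicate 1 they gave 1, and the count was 4, all lower, in the deposited table and 12 by array weights.

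At 18 h, 3 features passed as lower in oleic acid than in saline mice, the only calls of oleic acid against saline with 31 arrays, and all 3 were chosen after their values were seen. They stood high on the saline 18 h arrays, so the calls are not a fall below the level of other saline mice. Olfr73, an olfactory receptor gene with its probe on chromosome 2 from 87874513 to 87874572 (mm9), was at -6.98 ± 0.25 (SD, n = 3) in oleic acid and -2.65 ± 1.40 (SD, n = 2) in saline mice (limma adjusted p = 0.000889). A probe without a gene name on chromosome 11 from 99441298 to 99441356 also passed (limma adjusted p = 0.00227), and an intergenic RNA probe on chromosome 9 from 36511672 to 36511731 too (limma adjusted p = 0.00772). All 3 were above background on both saline 18 h arrays and on none of the 3 oleic acid 18 h arrays, so the folds are lower bounds, at least 5.13-fold, 3.63-fold and 4.28-fold lower. Olfr73 reached -1.66 and -3.64 on the saline 18 h arrays and at most -5.18 on any other array with a value. The saline 18 h arrays shared slide 3 with the 4 h arrays while the oleic acid 18 h arrays were on slide 4, and treatment and slide cannot be told apart at this time. Of 26 neutrophil markers, 0 passed and the median was 0.30 (preset adjusted p = 0.00147, and adjusted p = 0.888 with an estimated correlation), which turned to -0.09 with slide as a fixed term and the saline groups merged; Slfn4 differed by 1.26 (0.01 to 2.52). Of 21 Nrf2 genes, 0 passed and the median was 0.12 (preset adjusted p = 0.00749, and adjusted p = 0.888 with an estimated correlation). Gsta1, a glutathione transferase, differed by 1.13 (-0.31 to 2.57). Adjusted over the list alone 0 members of either list passed. The count of 3, with 167 genes at an unadjusted p under 0.05, was 5 with 29 arrays, where 2 probes without a gene name joined the same 3 features. The deposited table called none of these 3 and gave 5 other features, all lower, among them Htr4, a serotonin receptor (-1.58, adjusted p = 7.13e-05, against 1 with 31 arrays), Mars2, the mitochondrial methionyl-tRNA synthetase (-1.87, adjusted p = 0.0147, against 1), and the olfactory receptor Olfr484 (-1.80, adjusted p = 0.033, against 1). Quantile normalization, the fit to the 18 h groups alone and the saline 24 h mice as the control each gave 0. Without saline 18 h replicate 2 the count was 9, and without oleic acid 18 h replicate 1 or replicate 2 it was 2.

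At 24 h, the preset camera test called 9 lists, all higher, and of these cholesterol synthesis is described, though 2 others had larger medians. The 25 genes had a median of 0.20 beside a median of -0.12 over all genes (preset adjusted p = 0.0118, and adjusted p = 0.967 with an estimated correlation). Fdft1, the squalene synthase, differed by 0.49 (-0.33 to 1.30) and the sterol reductase Tm7sf2 by -0.48 (-1.29 to 0.32). The 31 ribosomal protein genes had a median of -0.25 that turned to 0.07 with quantile normalization and to 0.08 in the deposited table (preset adjusted p = 0.303, and adjusted p = 0.967 with an estimated correlation). Adjusted over the list alone 0 members of both lists passed, and in limma 0 genes passed with 192 at an unadjusted p under 0.05, or 4 with 1185 on 29 arrays, 2 higher and 2 lower. Of these 4, chosen after their values were seen, Zfand4, a zinc finger protein, rose at least 1.34-fold (limma adjusted p = 0.0317, against 1 with 31 arrays and 0.874 in the deposited table). The others were the transcript B130024M06Rik (at least 2.12-fold higher, which also passed in the deposited table), the transcript AA267875 (at least 2.35-fold lower) and an intergenic RNA on chromosome 15 (at least 13.7-fold lower). All 4 lay below background on every array of 1 treatment, so the folds are lower bounds. Without saline 24 h replicate 1 the 31 arrays gave 2 genes and without oleic acid 24 h replicate 3 they gave 1.

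Saline mice were compared between 18 and 24 h and the times from 1 to 4 h, to see which genes differed with time in animals without the fatty acid. Here 10 genes rose and 16 fell over 4 late and 9 early arrays, with an adjusted p under 0.05 in limma and an unadjusted p under 0.05 for 1091. Gsta1, a glutathione transferase, rose 7.59-fold, from -3.36 ± 0.67 (SD, n = 9) to -0.38 ± 0.53 (SD, n = 4) over arrays, with the fold taken from the mean of the means per time (adjusted p = 0.00856), and Hes2, a transcriptional repressor of the Hes family, rose 2.32-fold (adjusted p = 0.00522). Per1, a clock gene that glucocorticoids induce, fell by 2.38 on the log2 scale, a 5.19-fold fall (adjusted p = 0.0399), and Pdk4, the fasting-induced kinase that shuts pyruvate oxidation, was 4.3-fold lower (adjusted p = 0.035). Il1r2, the decoy receptor of interleukin 1, was 4.06-fold lower (adjusted p = 0.0381), the poly(A)-binding protein gene Pabpc1l 3.32-fold lower (adjusted p = 0.0203) and the poly(A) polymerase gene Tent5b 3.2-fold lower (adjusted p = 0.0411). Of the 10 genes that rose, 3 are the features called at 18 h, which lay above background on the saline 18 h arrays alone among the saline arrays. The probes lie at 78090411 to 78090470 on chromosome 9 for Gsta1, 151536406 to 151536465 on chromosome 4 for Hes2 and 68923364 to 68923423 on chromosome 11 for Per1 (mm9).

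By list, glucocorticoid-induced genes and metallothioneins had the lowest median of the described lists in late saline mice. Of 22 measured members 2 fell over all genes and 9 adjusted over the list alone, with a median of -0.98, and Per1 and Pdk4 were those over all genes. The preset camera adjusted p was 1.65e-20, against an adjusted p = 0.198 with an estimated correlation. With 29 arrays 10 members fell, among them Ddit4, an inhibitor of mTORC1 (difference -1.91, adjusted p = 0.000846, against 0.0744 with 31 arrays and 0.000128 in the deposited table), and Errfi1, an inhibitor of the epidermal growth factor receptor (difference -1.75, adjusted p = 0.00442, against 0.344 and 0.00127). Of 17 clock genes 1, Per1, fell over all genes and 2 adjusted over the list alone, with a median of -0.67, a preset adjusted p = 8.52e-07 and an adjusted p = 0.0682 with an estimated correlation; the clock repressor Nr1d1 had a difference of -1.96 (-3.09 to -0.82). Of 20 immediate early genes 0 passed over all genes and 2 fell adjusted over the list alone, with a median of -0.42 (preset adjusted p = 2.17e-07, and adjusted p = 0.401 with an estimated correlation). Differences were -1.04 for the small Maf factor Maff (-1.72 to -0.36) and -0.92 for the orphan nuclear receptor Nr4a2 (-1.53 to -0.31). Of 26 neutrophil markers only Il1r2 fell, over all genes and adjusted over the list alone, and the median was -0.63 (preset adjusted p = 7.18e-09, and adjusted p = 0.329 with an estimated correlation). Of 35 PPAR targets only Pdk4, which the glucocorticoid list also holds, fell, over all genes and adjusted over the list alone, and the median was -0.19 (preset adjusted p = 2.26e-06, and adjusted p = 0.703 with an estimated correlation); Angptl4 had a difference of -1.56 (-2.65 to -0.47). The 19 feedback genes of NF-kappaB had a median of -0.17 (preset adjusted p = 0.000722, and adjusted p = 0.21 with an estimated correlation), with 1 lower adjusted over the list alone, and the 19 platelet markers one of -0.42 with 0 passing (preset adjusted p = 7.53e-06, and adjusted p = 0.38 with an estimated correlation). The 20 coagulation genes had a median of -0.20 with 0 passing (preset adjusted p = 0.00365, and adjusted p = 0.56 with an estimated correlation). The heat shock list was not called by camera (preset adjusted p = 0.0934, and adjusted p = 0.879 with an estimated correlation). Its median was 0.36 over 16 members, with 2 higher adjusted over the list alone. Hsph1, a chaperone of the Hsp110 family, had a difference of 1.07 (0.40 to 1.74).

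With 29 arrays 331 genes rose and 341 fell between early and late saline mice, all 26 of the first fit among them, and the deposited table gave 269 and 354. The deposited table called 408 of the 672 genes and 20 of the 26, and quantile normalization of the 29 arrays called 434 and 18. Ppp1r3c, a glycogen-targeting subunit of protein phosphatase 1, rose by 1.65 with 29 arrays (adjusted p = 8.16e-05, against 0.0606 with 31 and 5.79e-05 in the deposited table). Foxo3, a transcription factor of the fasting and stress response, fell by 2.11 (adjusted p = 1.26e-05, against 0.0632 and 1.88e-06), and Csrnp1, an immediate early nuclear protein, fell by 2.06 (adjusted p = 0.000917, against 0.0979 and 0.00015). The same comparison in oleic acid mice, added after seeing the data, gave 524 higher and 808 lower genes on 29 arrays, with 2.68 for Gsta1, -2.01 for Per1, -1.65 for Pdk4 and -2.15 for Il1r2, all 4 past the threshold. Of the 672 genes called in saline mice, 667 had the same direction and 488 also passed in oleic acid mice, and the difference between both treatments passed for 3 when adjusted over these 672. These times also differ by slide, and the labels give no hour of harvest. Only slide 3 holds saline mice of both 4 and 18 h, and within it Per1 differed by -3.50, Il1r2 by -3.18 and Pdk4 by -3.10, all past the threshold, while Gsta1 differed by 1.70 (adjusted p = 0.122). The count of 26 with 31 arrays was 0 without saline 24 h replicate 1, 1 without saline 18 h replicate 1, between 11 and 15 without saline 1 h replicate 2 or 3, saline 1.5 h replicate 1 or 2, saline 3 h replicate 1 or 2, saline 4 h replicate 2, saline 18 h replicate 2 or saline 24 h replicate 2. Median centring gave 0. The count of 672 with 29 arrays was 178 without saline 18 h replicate 1, 204 without saline 24 h replicate 1 and 343 without saline 24 h replicate 2. It was 388 without saline 3 h replicate 2, 399 without saline 1.5 h replicate 1 and 401 without saline 18 h replicate 2.

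**Figure D4:**
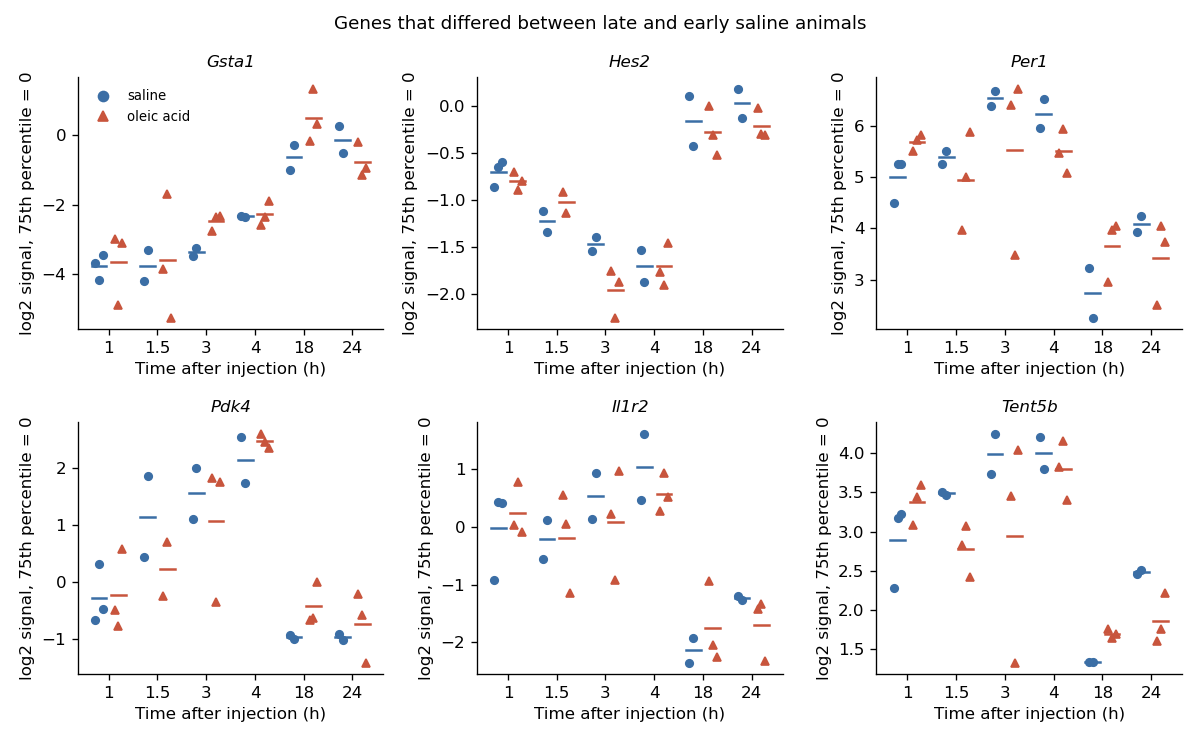
Expression of Gsta1, Hes2, Per1, Pdk4, Il1r2 and Tent5b (log2 relative to the 75th percentile of the array) is plotted for every array by time, with bars at the group means of all arrays. In saline mice Gsta1 averages -0.38 at 18 and 24 h against -3.36 from 1 to 4 h, and Per1 averages 3.41 against 5.70 over arrays, while folds in the text weigh each time equally.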

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

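Settings named here with 29 arrays, with 5 further arrays left out or with covariates, and comparisons of time within oleic acid mice, were chosen after the results were seen. The cause of a changed count was not tested unless fewer arrays or genes made it. Of the 672 genes called in saline mice with 29 arrays, 670 kept their direction in the deposited table and 2 turned. Medians of lists without a call by an estimated correlation turned sign between 31 and 29 arrays for 12 of 43 lists at 1.5 h, 19 at 3 h, 16 over 1 to 4 h and 15 for the difference of effects. Over the settings fixed in advance, named genes and list medians gave 2106 values that kept their direction without a recorded change of call. Another 25 lost a call, 29 gained one, 46 uncalled values turned direction and 0 called values did. In the added fit 221 kept their direction without a recorded change, 21 gained a call and 5 uncalled values turned. For list medians and the omission of single arrays only the direction was compared. No list counted as called here, so none could turn as a called value. Over 1 to 4 h the count of 0 genes (limma; 880 at an unadjusted p under 0.05) stayed 0 in every setting except array weights, 2062 with 31 arrays and 1 with 29, and the omission of oleic acid 1.5 h replicate 1 or saline 4 h replicate 1 from the 29 arrays, 1 each. Those weights ran from 0.000617 to 24.2 in an estimate that stopped before convergence. With 31 arrays they gave 4564 genes at 1 h, 1077 at 1.5 h, 12 at 4 h, 4 at 24 h, 4 over 18 and 24 h, 2 for the difference of effects and 906 for saline mice over time. With 29 arrays they gave 2475 at 1 h, 2 at 4 h, 2 at 24 h, 2 over 18 and 24 h and 530 for saline mice. Normexp gave 1 gene at 18 h and 5 in saline mice. Quantile normalization gave 1 at 4 h, 0 at 18 h, 2 at 24 h and 15 in saline mice. Median centring gave 1 at 18 h and 0 in saline mice. The deposited table gave 2 at 3 h, 4 at 4 h, 5 at 18 h, 1 at 24 h and 623 in saline mice. No filter gave 12 in saline mice. The filter on all 31 arrays, which tests fewer genes, gave 0 at 18 h and 17 in saline mice. Kept outlier spots gave 1 at 18 h, 1 at 24 h and 10 in saline mice. The fit to the compared groups alone, the moderation with a trend and the saline 24 h control gave 0 at 18 h, and an adjusted p under 0.01 left 6 in saline mice. Slide as a random term (correlation 0.0988) gave 12 in saline mice, as a fixed term 5 at 3 h, and with saline groups merged 2 at 3 h and 0 at 18 h. With the 12 groups kept apart, the fixed term could not be fitted for 18 h, the mean over 18 and 24 h, the difference of effects and saline mice over time. Replicate number as a block gave 1 at 24 h. Arrays of the same number correlated between -0.768 and 0.614 over 13 pairs, and others between -0.614 and 0.783 over 26.

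With 29 arrays there were 5 genes at 4 h, 5 at 18 h, 4 at 24 h, 2 over 18 and 24 h and 672 in saline mice. Both arrays left out are oleic acid arrays, so the saline differences stay as they were while the median standard error goes from 0.353 to 0.187. On those arrays the deposited table gave 5 at 4 h and 550 in saline mice. Quantile normalization gave 2 at 1.5 h, 1 at 4 h, 2 at 24 h and 618 there. Normexp gave 1 at 24 h, 1 over 18 and 24 h and 530 there. Slide as a random term (correlation -0.0481) gave 5 at 4 h, 5 at 18 h, 4 at 24 h, 4 over 18 and 24 h and 902 there. The replicate block gave 1, 5, 2, 4 and 687 for the same. Without the 5 further arrays, which leaves a lone saline 18 h array assumed to vary like the others, there were 14 at 1.5 h, 1 at 4 h, 83 at 18 h, 5 at 24 h, 49 over 18 and 24 h, 16 for the difference of effects and 467 in saline mice. The share of spots above background as a covariate gave 3 at 4 h, 10 at 18 h, 5 at 24 h, 3 over 18 and 24 h and 921 in saline mice. The deposited table with it gave 7, 7, 2, 1 and 944. With the 75th percentile too it gave 5 at 4 h, 11 at 18 h, 3 at 24 h and 1777 in saline mice. Leaving out 1 array at a time gave 0 to 0 genes at 1 h, at 1.5 h, over 1 to 4 h and for the difference of effects, 0 to 141 at 3 h, 0 to 2 at 4 h, 2 to 9 at 18 h, 0 to 2 at 24 h, 0 to 4 over 18 and 24 h and 0 to 21 in saline mice. With 29 arrays these ranges were 0 to 1 at 1 h, 0 to 5 at 1.5 h, 1 to 111 at 3 h, 1 to 27 at 4 h, 4 to 32 at 18 h, 0 to 15 at 24 h, 0 to 1 over 1 to 4 h, 2 to 14 over 18 and 24 h, 0 to 10 for the difference of effects and 178 to 812 in saline mice. In saline mice the values between these were 518 and 602 without 1 h replicates 2 and 3, 399 and 479 without 1.5 h replicates 1 and 2, and 543 and 388 without 3 h replicates 1 and 2. They were 752 and 615 without 4 h replicates 1 and 2, 401 without 18 h replicate 2, and 204 and 343 without 24 h replicates 1 and 2. Between 51.18% and 66.19% of spots lay well above background on 24 arrays, so genes near background are measured by surrogate signals there.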

Other observations

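The tests of slide as the whole cause, of clock phase, of the share of spots for the clock genes, of the saline 4 h array and the random splits with 31 arrays were chosen after the result was seen, as were the comparisons of time and the models on 29 arrays in the next paragraph.

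Genes also differed between times in oleic acid mice, here with 29 arrays. All oleic acid arrays of 18 and 24 h were on slide 4 and those of 1 to 4 h on other slides. Late and early times cannot be told apart from slide there. Between 1 to 4 h and 18 to 24 h, 11 of 22 glucocorticoid-induced genes fell in oleic acid mice with a median of -0.75 (preset camera adjusted p = 8.49e-10, and adjusted p = 0.335 with an estimated correlation), and 5 of 17 clock genes fell with a median of -0.67 (preset adjusted p = 0.000855, and adjusted p = 0.335 with an estimated correlation). Within slide 3, where saline mice of 4 and 18 h stand side by side, 13 of 22 glucocorticoid-induced genes and 9 of 17 clock genes fell among 439 higher and 1171 lower genes (5828 at an unadjusted p under 0.05 in limma), with medians of -1.73 (preset adjusted p = 1.15e-09, and adjusted p = 0.441 with an estimated correlation) and -1.61 (preset adjusted p = 0.00244, and adjusted p = 0.441 with an estimated correlation). Other lists differed there too, with 9 of 31 ribosomal protein genes lower (median -0.51, preset adjusted p = 6.4e-09, and adjusted p = 0.53 with an estimated correlation) and medians of -1.14 for neutrophil (preset 0.000294), 0.84 for B cell (preset 1.29e-05) and 1.23 for adipose markers (preset 0.0118), each with an adjusted p = 0.551 with an estimated correlation. These are 2 arrays against 2, among them saline 4 h replicate 2 with the highest cytokine mean and saline 18 h replicate 2 with 77.53% of spots above background. Between 18 and 24 h within slide 4, 3 genes rose and 0 fell in oleic acid mice (558 at an unadjusted p under 0.05 in limma). Between 1.5 and 3 h on slide 2, with both treatments averaged, 0 genes passed in limma over 3 saline and 3 oleic acid arrays and 2833 had an unadjusted p under 0.05, with medians of 1.28 over the immediate early genes (preset adjusted p = 9.76e-19), 0.89 over platelet (preset 1.34e-08) and -0.48 over cardiac markers (preset 5.55e-06), each with an adjusted p = 0.679 with an estimated correlation. Saline 1.5 h replicate 2, with a cardiac mean of 2.97, is among these arrays. In a model with terms for time and treatment but none for slide, 7088 genes differed between times. Slides followed time, so this count cannot be credited to time alone. For treatment 0 genes passed, with 3552 at an unadjusted p under 0.05. An effect of oleic acid that differs between times passed for 2 genes, and for 0 with 31 arrays (203 at an unadjusted p under 0.05). In 2580 tests of 172 described genes between pairs of times, made with all 31 arrays, 0 passed, with a smallest adjusted p of 0.307.

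Late and early saline mice differed in 26 genes, and in 672 with 29 arrays. Causes were tested on 61 genes called between the saline mice of slide 4, all of 24 h, and those of 1, 1.5 and 3 h. For these 61 the share of spots above background is argued against as the whole cause. With it as a covariate their median difference kept 0.981 of its size. This was not computed for the 26 or 672 genes, and saline 4 and 18 h did not enter that difference. Slide as the whole cause is argued against for the same 61 genes as a set, not for each of them. Of them 49 kept the direction within slide 3 and 23 (37.7%) passed there in it, adjusted over these genes. Over all genes, limma called 439 higher and 1171 lower there, with 5828 at an unadjusted p under 0.05. It is 2 arrays against 2, with saline 4 h replicate 2 and saline 18 h replicate 2 (77.53% of spots above background) among them. That share was not a covariate within slide 3. A part from slide stays open, as the 61 genes kept 0.492 of their difference within slide 3 (bootstrap 0.237 to 0.75 over genes, which are not independent), between the bounds of 0.2 and 0.5 set for it. Stress of injection and anaesthesia that has passed by 18 h, or the hour of the day at harvest, could bring the fall of Per1 and Pdk4, and neither was tested.

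Clock genes set saline 1 h replicate 3 apart from saline 1 h replicates 1 and 2, and oleic acid 24 h replicate 3 apart from its group. Signal strength is argued against, because Dbp differed by 4.18 between saline 1 h replicates 3 and 2, whose shares of spots above background were within 1 percentage point. Another phase of the clock at harvest may explain it, and no label gives the hour. Over 15 clock genes the difference correlated, across genes, which are not independent replicates, with the axis that separates the other times, with a size of 0.84, and of 0.86 for oleic acid 24 h replicate 3. An oleic acid mouse under the label of saline 1 h replicate 3 stays open, since without the clock genes it correlated at 0.939 and 0.975 with the saline 1 h arrays and at 0.993, 0.96 and 0.988 with the oleic acid 1 h arrays, an overlap with -0.054 between the lowest saline and the highest oleic acid value, and the lowest of each belong to arrays with over 70% of spots above background.

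Saline 4 h replicate 2 had the highest mean of 35 cytokine and chemokine genes among all 31 arrays, 0.42 against -1.08 on saline 4 h replicate 1. An oleic acid mouse under a saline label stays open, because the mean lay 0.92 above the highest oleic acid 4 h array but the array was picked for having the highest mean, which fixes the outcome of that test. More neutrophils in the piece of lung may account for part of it, as 26 neutrophil markers had a median 0.9 above the other 4 h arrays, though some of these markers are themselves induced by cytokines.

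For the other counts, random splits within times, or across times for saline mice alone, were compared with the real groups. Over 1 to 4 h the real count was 0 and the highest other 11, over 18 and 24 h it was 0 and 2, and for the difference of effects 0 and 2, and since every one of the 100 splits gives at least 0 genes, the splits add nothing for these 3. At 1 h the 10 possible splits are too few for a share under 0.05; the real count and the highest other were both 0. For late against early saline mice, 5 of 100 divisions of the 13 saline arrays gave at least 26 genes with 31 arrays in the fit, the real one included, with 110 as the highest other count, so chance is not excluded. With 29 arrays, a fit chosen after seeing the data, 2 of 100 divisions gave at least 672, the real one included. The highest other count was 4269. That share is under 0.05, but the divisions mix times and slides within groups, so they do not exclude chance there either. The division with 4269 genes put saline 1 h replicate 3, both saline 1.5 h arrays and saline 18 h replicate 2 into the late group. With 29 arrays 6 divisions gave at least 100 genes, this one included, and what they share was not tested.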
